A study of Mus musculus with 21 samples.

How the data were processed

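RNA-seq was analysed from 21 libraries of mouse bone marrow-derived macrophages. Per the labels' protocols, cells were grown in M-CSF for 5 days, treated with JQ1 or SF2523 and then stimulated with LPS or IL4, mRNA was extracted with a Qiagen kit, and libraries were sequenced on an Illumina HiSeq4000. Groups came from the exposure and drug labels, 3 libraries in each of 7 groups. The replicate numbers used here follow the order of deposition and name libraries only. Labels give no replicate number, batch or date. Library titles hold codes with the letter A for NS, LPS, IL4 and LPS with JQ1 and the letter B for IL4 with JQ1 and both SF2523 groups, and what the letters stand for is not given, so a difference between A and B libraries cannot be separated from the effect of SF2523 in either stimulus, from that of JQ1 with IL4, from SF2523 vs JQ1 with LPS or from the difference of the JQ1 effect between stimuli.

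The deposited table holds RPKM, reads per kilobase of exon scaled to the assigned reads of the library, computed by the authors. Per the submitters' processing notes, bcl2fastq, STAR version 2.6.1a, featureCounts version 1.6.2 and the genome build GRCm38 were used. Their parameters, and whether counting used strand, are not given in the sources used here, so reads of a gene cannot be told from those of an overlapping or antisense gene, and near-identical paralogs such as Fcgr, H2, Ifit or histone genes may share reads. RPKM divides by the total of each library, so a group in which a few genes take many reads shifts all others. The values of each library summed to 321610 to 386680 RPKM on average per group, the lowest in IL4 with JQ1 and the highest in LPS with SF2523.

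The table had 54232 genes, 29392 of them above 0 in at least 1 library. Symbols present more than once (96 symbols, 194 entries) were reduced to the entry with the higher mean, leaving 54134. In GENCODE M21, a GRCm38 annotation, 53191 entries had a matching symbol. Gene lengths and library totals were recovered together from the steps of the RPKM values, and 100% of the values above 0 came out as whole reads within 0.01 read. The implied length equalled the exon union of GENCODE M21 for 95.3% of entries with a unique symbol. RPKM, not the recovered reads, remained the basis of the tests. The recovered totals were 20936387 to 51382355 assigned reads per library. A floor of 3 reads in 1 kb of exon was 0.0584 to 0.143 RPKM, and since reads carry no molecular identifiers, floors cover counting error only. Pairs of replicates were compared by chi-square on the recovered reads. The statistic per degree of freedom was 1.64 to 16.1, so no pair agreed within sampling noise and all 21 libraries were kept as separate. Correlations within groups were 0.9942 to 0.9979.

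Genes with RPKM of at least 1 in at least 3 libraries were tested, 11112 in all. limma version 3.58.1 in R 4.3.3 was fitted to log2(RPKM + 1) with 1 mean per group over all 21 libraries, so that groups share their estimate of the spread (14 residual degrees of freedom, against 4 for 2 groups alone), with moderated variances and a trend on mean expression. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Calls with an absolute log2 fold change of at least 1 were counted as well. Comparisons were LPS vs NS, IL4 vs NS, each drug against its drug-free stimulus, SF2523 vs JQ1 within each stimulus, and the difference of each drug's effect between stimuli. An exact permutation test of 3 against 3 libraries cannot give a p below 0.10, so p-values rest on the model.

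There were 18 gene lists and 10 marker lists, written with the test, the filter, the comparisons, the rule for named genes and most alternatives before the data were examined. The gene lists were inflammatory cytokines and chemokines, NF-kB feedback, type I interferon response, IL4-STAT6 activation, MHC class II, MHC class I, tumour-promoting macrophage genes, MYC and ribosome biogenesis, proliferation, genes known to rise under BET inhibitors, FOXO targets, glycolysis and hypoxia, sterol synthesis, lysosome, macrophage identity, integrated stress response, immediate early genes, and complement, scavenger and Fc receptors. Each was tested with limma's camera (preset correlation 0.01) against all other tested genes, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members were also counted after adjustment over the list alone. The rule named the 10 largest rises and 10 largest falls per comparison (5 for the differences between stimuli) among called genes with a mean of at least 5 RPKM in the higher group and no overlap of libraries, up to 4 members per list by smallest p, and 20 fixed genes, of which the text uses part. For 3 against 3 libraries chance gives no overlap for 10% of genes.

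Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at RPKM 5, rescaling each library to a common RPKM sum, median-ratio scaling, quantile normalization, array weights, a fit of the compared groups only, and each replicate left out in turn. Voom on the recovered reads, removal of each library's trend on exon length and a fit without the NS libraries were added after the data were seen. Overlaps were set beside the overlap of independent lists, and correlations between comparisons beside 20 simulations of unchanged groups against the same controls. Counts at 2-fold or more depended on the pseudocount and the scaling: for LPS vs NS they were 1008 higher and 310 lower, 1588 and 497 with a pseudocount of 0.1, and 813 and 437 with median ratios.

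The fit was tested on simulated data, with 200 of the 11112 genes changed in each comparison, 50 at each of log2 0.25, 0.5, 1 and 2. Recovered in the right direction at those sizes were 38%, 74%, 90% and 94% for LPS vs NS, 56%, 84%, 92% and 96% for IL4 vs NS, 46%, 92%, 92% and 96% for LPS with JQ1 vs LPS, 52%, 86%, 96% and 100% for LPS with SF2523 vs LPS, 36%, 84%, 94% and 96% for IL4 with JQ1 vs IL4, and 54%, 74%, 96% and 96% for IL4 with SF2523 vs IL4. For SF2523 vs JQ1 they were 48%, 82%, 92% and 94% with LPS and 40%, 88%, 86% and 94% with IL4. For the differences between stimuli they were 16%, 54%, 86% and 100% for JQ1 and 30%, 60%, 84% and 96% for SF2523. Of the 10912 unchanged genes, 4 to 23 were called per comparison. The simulated noise was independent between genes, without a shift of scaling or a trend on exon length. In the data, 64.4% to 82.2% of genes were called in the comparisons of 2 groups. These rates therefore check the fit and do not give the share of false calls in the data. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.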

Results

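The series holds bulk RNA-seq of mouse bone marrow-derived macrophages, primary macrophages grown from marrow cells in the growth factor M-CSF. After 5 days of culture, cells received JQ1 or SF2523 and then LPS or IL4. JQ1 displaces BET proteins (BRD2, BRD3, BRD4), which read acetylated histones, from chromatin. SF2523 is described by the submitters as an inhibitor of both PI3K and BRD4. LPS is the bacterial lipopolysaccharide that activates macrophages through Toll-like receptors, and IL4 is the cytokine that drives alternative activation through STAT6. The 21 libraries fell into 7 groups of 3: NS, LPS, IL4, LPS with JQ1, IL4 with JQ1, LPS with SF2523 and IL4 with SF2523. NS is printed as the labels give it, with no drug entered. By the labels no library received a drug without LPS or IL4, and doses and times of the drugs are not given in the labels. The labels do not say that the 3 libraries of a group came from separate cultures or animals, so every p-value below measures the spread between libraries, which may be technical.

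The deposited values were RPKM, and whole reads could be recovered from them. Between 20936387 and 51382355 reads were assigned to genes per library, with group means of 31418000 ± 2790800 in NS, 27737000 ± 421580 in LPS, 34247000 ± 6624200 in IL4, 35201000 ± 12378000 in LPS with JQ1, 33556000 ± 15621000 in IL4 with JQ1, 26351000 ± 2754200 in LPS with SF2523 and 28656000 ± 4356500 in IL4 with SF2523 (SD, n = 3). A floor of 3 reads in a gene of 1 kb corresponded to 0.0584 to 0.143 RPKM, depending on the library. Fold changes were computed on log2(RPKM + 1) and therefore understate the change of genes with low values. Levels are given as mean RPKM ± SD over the 3 libraries of a group (n = 3), and log2 fold changes, where an error is printed, with their standard error.

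The groups separated cleanly, and the libraries labelled NS lay beside those that received JQ1. The first principal component held 51.5% of the variance and the second 29%. NS libraries lay at -40.95 to -39.51 on the first component, LPS with JQ1 at -45.98 to -44.75 and IL4 with JQ1 at -32.47 to -31.54, against 17.88 to 18.5 for LPS and 42.65 to 43.75 for IL4. LPS with SF2523 (15.69 to 16.2) and IL4 with SF2523 (39.14 to 40.82) stayed near their drug-free counterparts on the first component, but the third (8.87% of the variance) set them apart, with LPS at -26.45 to -23.46 against 18.14 to 21.4 with SF2523, and IL4 at -15.84 to -10.16 against 13.85 to 21.35. Across genes, which are not independent replicates, the NS mean correlated with LPS with JQ1 at Pearson's r = 0.984 and with IL4 with JQ1 at 0.983, against 0.92 for LPS and 0.903 for IL4. JQ1 moved 759 genes at least 2-fold in the same direction under both stimuli. On a scale where the drug-free mean is 0 and the JQ1 mean is 1, NS had a median position of 0.955 over those genes (quartiles 0.843 to 1.061). Every comparison with NS below is therefore a comparison with the libraries labelled NS, whatever those cells had received.

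**Figure D1:**
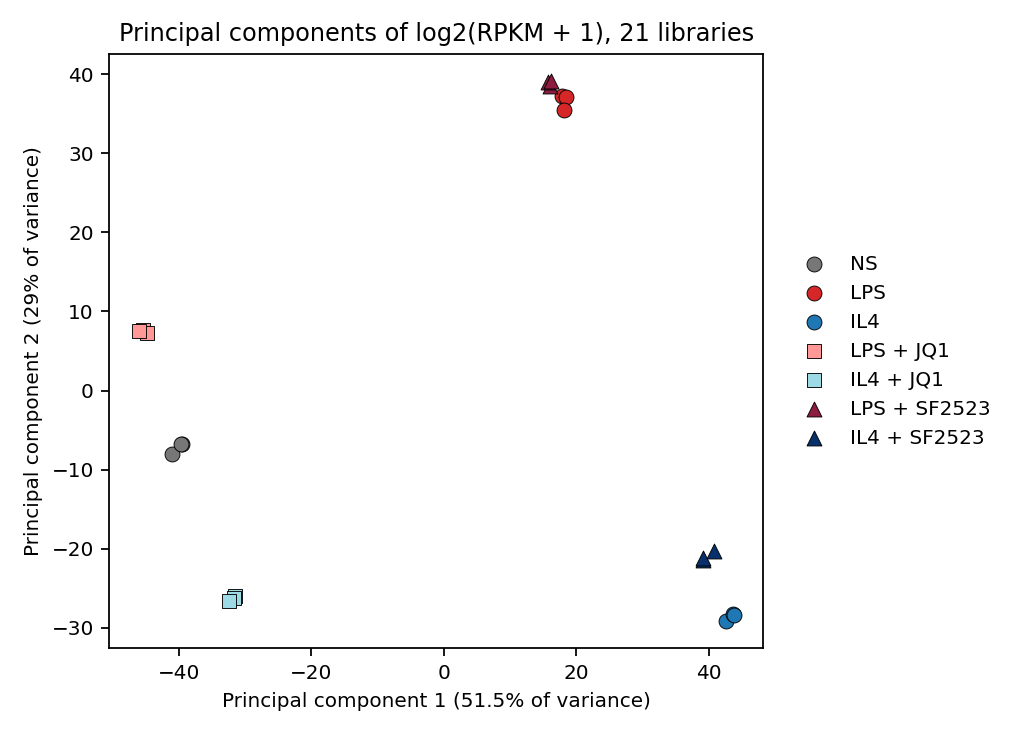
Principal components of log2(RPKM + 1) over the 11112 tested genes, with the first component (51.5% of the variance) on the x axis and the second (29%) on the y axis. Each point is 1 of 21 libraries, coloured by group; the 3 NS libraries sit near the JQ1 libraries on the first component, and on these 2 components the SF2523 libraries sit near the drug-free libraries of the same stimulus.

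No member of the T cell, NK cell, dendritic cell, mast cell or erythroid marker lists passed the expression filter. Of the B cell list 2 genes were tested, of the eosinophil list 2, of the fibroblast list 2, of the osteoclast list 4 and of the neutrophil and precursor list 9. LPS replicate 3 stood apart: 57 genes reached RPKM 1 there while staying at or under 0.1 in each of the other 20 libraries, against at most 2 such genes in any other library. Msln, a mesothelial surface protein chosen here after its values were seen, was at 19.5 RPKM in that library. Genes of granulocyte precursors were present in all groups. Mpo, myeloperoxidase, was at 9.18 RPKM in NS, 39.9 in LPS, 50.1 in IL4, 1.83 in LPS with JQ1, 3.11 in IL4 with JQ1, 42.7 in LPS with SF2523 and 51.4 in IL4 with SF2523.

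LPS without drug was compared with NS to define the response to the bacterial stimulus. The libraries were marked by an interferon response. All 33 tested genes of the type I interferon list rose, with a median log2 fold change of 2.79 (limma camera adjusted p = 2.39e-16). Ifit3 (ENSMUSG00000074896, GRCm38 chromosome 19, 34583531 to 34588731), an interferon-induced antiviral gene, rose from 0.421 ± 0.14 to 53.3 ± 0.873 RPKM, a log2 fold change of 5.26 ± 0.09. Isg15, the interferon-induced ubiquitin-like modifier, rose from 8.25 ± 0.536 to 272 ± 2.25 RPKM, and Zbp1, a sensor of Z-form nucleic acids, rose by 5.14 on the log2 scale. The interferon-induced deubiquitinase Usp18 rose by 4.07, as did Oas3 by 4.05.

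The largest rise was that of Ccl5 (ENSMUSG00000035042, GRCm38 chromosome 11, 83525778 to 83530518), a chemokine that attracts T cells and monocytes, which went from 2.75 ± 0.394 to 360.2 ± 24.7 RPKM (log2 6.59 ± 0.07, limma adjusted p = 2.93e-22). Siglec1, a sialic acid-binding receptor of macrophages, rose from 2.11 ± 0.0908 to 135 ± 2.42 RPKM. The high-affinity IgG receptor Fcgr1 rose from 4.16 ± 0.39 to 189 ± 3.82, the acute-phase gene Saa3 from 151 ± 7 to 5487 ± 50.1, and the scavenger receptor Marco by 3.71 on the log2 scale. Arg1 (ENSMUSG00000019987, GRCm38 chromosome 10, 24915221 to 24927484), the arginase of alternatively activated macrophages, rose from 2.18 ± 0.22 to 55.3 ± 1.15 RPKM. Among always-reported genes, Il1b rose from 4.83 ± 0.517 to 18.5 ± 0.205, Il10 from 0.42 ± 0.154 to 6.84 ± 0.79 and Cd274, which encodes PD-L1, by 2.98 on the log2 scale. Il6 rose by 0.67 but reached only 0.639 ± 0.0322 RPKM. The inflammatory cytokine and chemokine list had 14 members higher, 5 lower and 1 not called of 20, which did not set it apart from other genes (camera adjusted p = 0.132, and 0.0309 with median-ratio scaling). Tnf was among those that fell, from 158 ± 3.53 to 52.2 ± 0.756 RPKM, while the monocyte chemokines Ccl2 (1.73) and Ccl7 (2.80) rose.

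Other groups moved too. All but 1 of the 29 proliferation genes rose and none fell (median 0.84, camera adjusted p = 2.41e-08), with the DNA replication genes Mcm3 at 1.63, Mcm5 at 1.48 and Mcm2 at 1.44. Of 18 MYC and ribosome biogenesis targets 15 rose and 2 fell (0.0203), of 12 MHC class I genes 10 rose and 2 fell (0.0184, and adjusted p = 0.222 with an estimated correlation), of 17 glycolysis and hypoxia genes 14 rose and 3 fell (0.0184, and adjusted p = 0.222 with an estimated correlation) and of 19 sterol synthesis genes 14 rose and 1 fell (0.0193, and adjusted p = 0.148 with an estimated correlation), all by limma camera. Downward, all 7 genes known to rise under BET inhibitors fell, with a median of -2.2 (camera adjusted p = 3.34e-06). They include the linker histone Hist1h1c, which went from 114 ± 1.73 to 4.9 ± 0.338 RPKM, and Brd2 (ENSMUSG00000024335, GRCm38 chromosome 17, 34112023 to 34122634), which went from 173 ± 4.04 to 33.3 ± 0.661 RPKM. Hexim1 (ENSMUSG00000048878, GRCm38 chromosome 11, 103116231 to 103119725), an inhibitor of the elongation kinase P-TEFb, went from 73.5 ± 1.01 to 35.4 ± 1.11. The NF-kB feedback genes had 3 members higher and 12 lower of 16 (8.77e-05), Nfkbie at -1.90. Immediate early genes had 1 higher and 10 lower of 11 (6.23e-06), Egr1 at -3.11 and Nr4a1 at -2.58. FOXO targets had 1 higher and 10 lower of 13 (6.28e-05), Txnip at -2.14 and Klf2 at -1.99. Lysosomal genes had 2 higher and 16 lower of 20 (1.76e-05), with the proteases Ctsb at -1.51 and Ctsd at -1.46. The p-values in parentheses are limma camera adjusted p. Apoe, the lipid carrier, fell from 465 ± 47.7 to 55.5 ± 3.23 RPKM, and the metallothioneins Mt1 (-2.69) and Mt2 (-2.94) fell.

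Not set apart by camera were the STAT6 list (10 higher, 11 lower, 4 not called, adjusted p = 0.381), MHC class II (7, 3 and 1, 0.538), tumour-promoting genes (10, 3 and 2, 0.0858, and 0.0196 with median-ratio scaling), macrophage identity (6, 10 and 3, 0.0945), the integrated stress response (6, 7 and 0, 0.658) and complement and scavenger receptors (9, 5 and 1, 0.259). The neutrophil and precursor markers had 8 higher and 1 lower (0.00536), and all 4 osteoclast markers rose (camera adjusted p = 0.00872, and adjusted p = 0.0528 with an estimated correlation). In total 5238 genes were higher and 3355 lower at a limma adjusted p under 0.05, 1008 and 310 of them by at least 2-fold. The counts of members adjusted over the list alone were the same for every list. The highest limma adjusted p of a gene named for LPS was 1.94e-07. The split of calls depended on scaling, since median-ratio scaling, which moved the median of all genes from 0.105 to -0.034, gave 4078 higher and 4585 lower, quantile normalization 3894 and 4968, and removal of the exon-length trend 4279 and 4304. Without LPS replicate 3 the counts were 5060 and 3315, and without NS replicate 1, the library with the lowest array weight (0.288), 5266 and 3212.

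IL4 without drug was compared with NS to define alternative activation. The classical IL4 genes dominated. All 25 tested genes of the IL4-STAT6 list rose, with a median log2 fold change of 3.56 (limma camera adjusted p = 8.89e-11). Arg1 rose from 2.18 ± 0.22 to 3182 ± 13.6 RPKM (log2 9.97 ± 0.07, limma adjusted p = 2.6e-24). Retnla (ENSMUSG00000061100, GRCm38 chromosome 16, 48842551 to 48844461), a secreted protein of alternatively activated macrophages, rose from 0.598 ± 0.131 to 1005 ± 39.4 RPKM, the lectin Mgl2 from 0.555 ± 0.0582 to 778 ± 2.13, the chitinase-like Chil3 from 52.4 ± 2.27 to 1426 ± 58.2 and the mannose receptor Mrc1 from 86.7 ± 4.35 to 736 ± 33.6.

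Some chemokines rose with them and others fell. Ccl8 rose by 7.64 on the log2 scale, Ccl12 by 6.82, Ccl24, which attracts eosinophils, by 6.44, Ccl7 by 4.58 and the macrophage elastase Mmp12 by 6.49, while Ccl3 fell from 156 ± 3.49 to 51 ± 0.565 RPKM and Ccl4 (-0.53), Cxcl1 (-0.73) and Cxcl2 (-0.41) also fell, these 4 chosen after their values were seen. Ch25h, the cholesterol 25-hydroxylase, rose by 6.21. The MHC class II list had 10 members higher and 1 lower of 11 (median 2.05, camera adjusted p = 0.00673), with H2-Aa from 1.01 ± 0.075 to 43.9 ± 0.798 RPKM, H2-Eb1 up by 4.38 and H2-Ab1 by 4.02. Growth-related groups rose as sets: all 18 MYC and ribosome biogenesis targets (median 1.17, camera adjusted p = 8.45e-06) and all 29 proliferation genes (1.21, 2.59e-08). Myc itself rose from 11.4 ± 0.539 to 40.2 ± 0.94 RPKM. Of 13 integrated stress response genes 9 rose and 2 fell (0.0423, and adjusted p = 0.184 with an estimated correlation by camera), among them the serine synthesis gene Psat1 at 2.54 and asparagine synthetase Asns at 2.63. Of 19 sterol genes 15 rose and none fell (0.0162, and adjusted p = 0.152 with an estimated correlation by camera). Interferon genes had 24 higher, 5 lower and 4 not called of 33, or 25 higher when adjusted over the list alone (camera adjusted p = 0.0388, and adjusted p = 0.207 with an estimated correlation).

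On the falling side were the formyl peptide receptor Fpr1, which senses bacterial peptides and went from 332 ± 6.56 to 19.7 ± 0.19 RPKM, Trem1 (-3.15), Apoe (-3.75) and Lyz2, lysozyme, which went from 33880 ± 1940 to 5431 ± 73.7. All 7 BET inhibitor genes fell (median -1.72, camera adjusted p = 4.48e-06), with Brd2 from 173 ± 4.04 to 38.6 ± 0.304 RPKM and Hexim1 from 73.5 ± 1.01 to 21.6 ± 0.427. FOXO targets had 1 higher and 10 lower of 13 (8.45e-06), led by Klf2, from 91.8 ± 10.3 to 6.04 ± 0.267 RPKM. Glycolysis genes had 3 higher and 12 lower of 17 (camera adjusted p = 0.000701, and adjusted p = 0.106 with an estimated correlation), with Pkm at -1.06. NF-kB feedback genes had 5 higher and 9 lower of 16 (0.015, and adjusted p = 0.162 with an estimated correlation by camera), Nfkbiz at -3.15 and Nfkbia at -1.60. Immediate early genes had 2 higher and 7 lower of 11 (camera adjusted p = 0.00819, and adjusted p = 0.0503 with an estimated correlation), with Egr1 at -2.86 but Egr2, a STAT6-induced factor, at 3.89. Macrophage identity genes had 8 higher and 9 lower of 19 (0.0388, and adjusted p = 0.207 with an estimated correlation and 0.0771 with median-ratio scaling, by camera), with Adgre1, which encodes F4/80, at -1.26. Tnf fell by 2.12 on the log2 scale. Il10 was not called, at 0.616 ± 0.132 RPKM with IL4 and 0.42 ± 0.154 in NS (limma adjusted p = 0.0785), and passed the threshold without NS replicate 1 (0.0191) or IL4 replicate 3 (0.049), with pseudocounts of 0.1 (0.0245) and 0.5 (0.0454), with rescaling to a common RPKM sum (0.0274) and with array weights (0.035).

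Camera did not set apart inflammatory cytokines (12 higher, 5 lower, 3 not called, adjusted p = 0.498), lysosomal genes (12, 8 and 0, 0.254, and 0.0461 with median-ratio scaling, with a positive median that other scalings turn negative and a downward test) or neutrophil markers (5, 4 and 0, 0.499). All 4 osteoclast markers rose (camera adjusted p = 0.00761, and adjusted p = 0.0701 with an estimated correlation), and 7 MHC class I genes rose while 5 fell. In total 6034 genes were higher and 3004 lower by limma, 1324 and 397 of them by at least 2-fold, and the median of all genes was 0.203 above 0 on the log2 scale. With median-ratio scaling, which moved that median to -0.008, the split was 4448 higher and 4563 lower, with quantile normalization 4258 and 4885, and with the length trend removed 4483 and 4501. Without NS replicate 1 the counts were 6050 and 2886. The highest limma adjusted p of a changed gene named for IL4 was 2.9e-06.

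**Figure D2:**
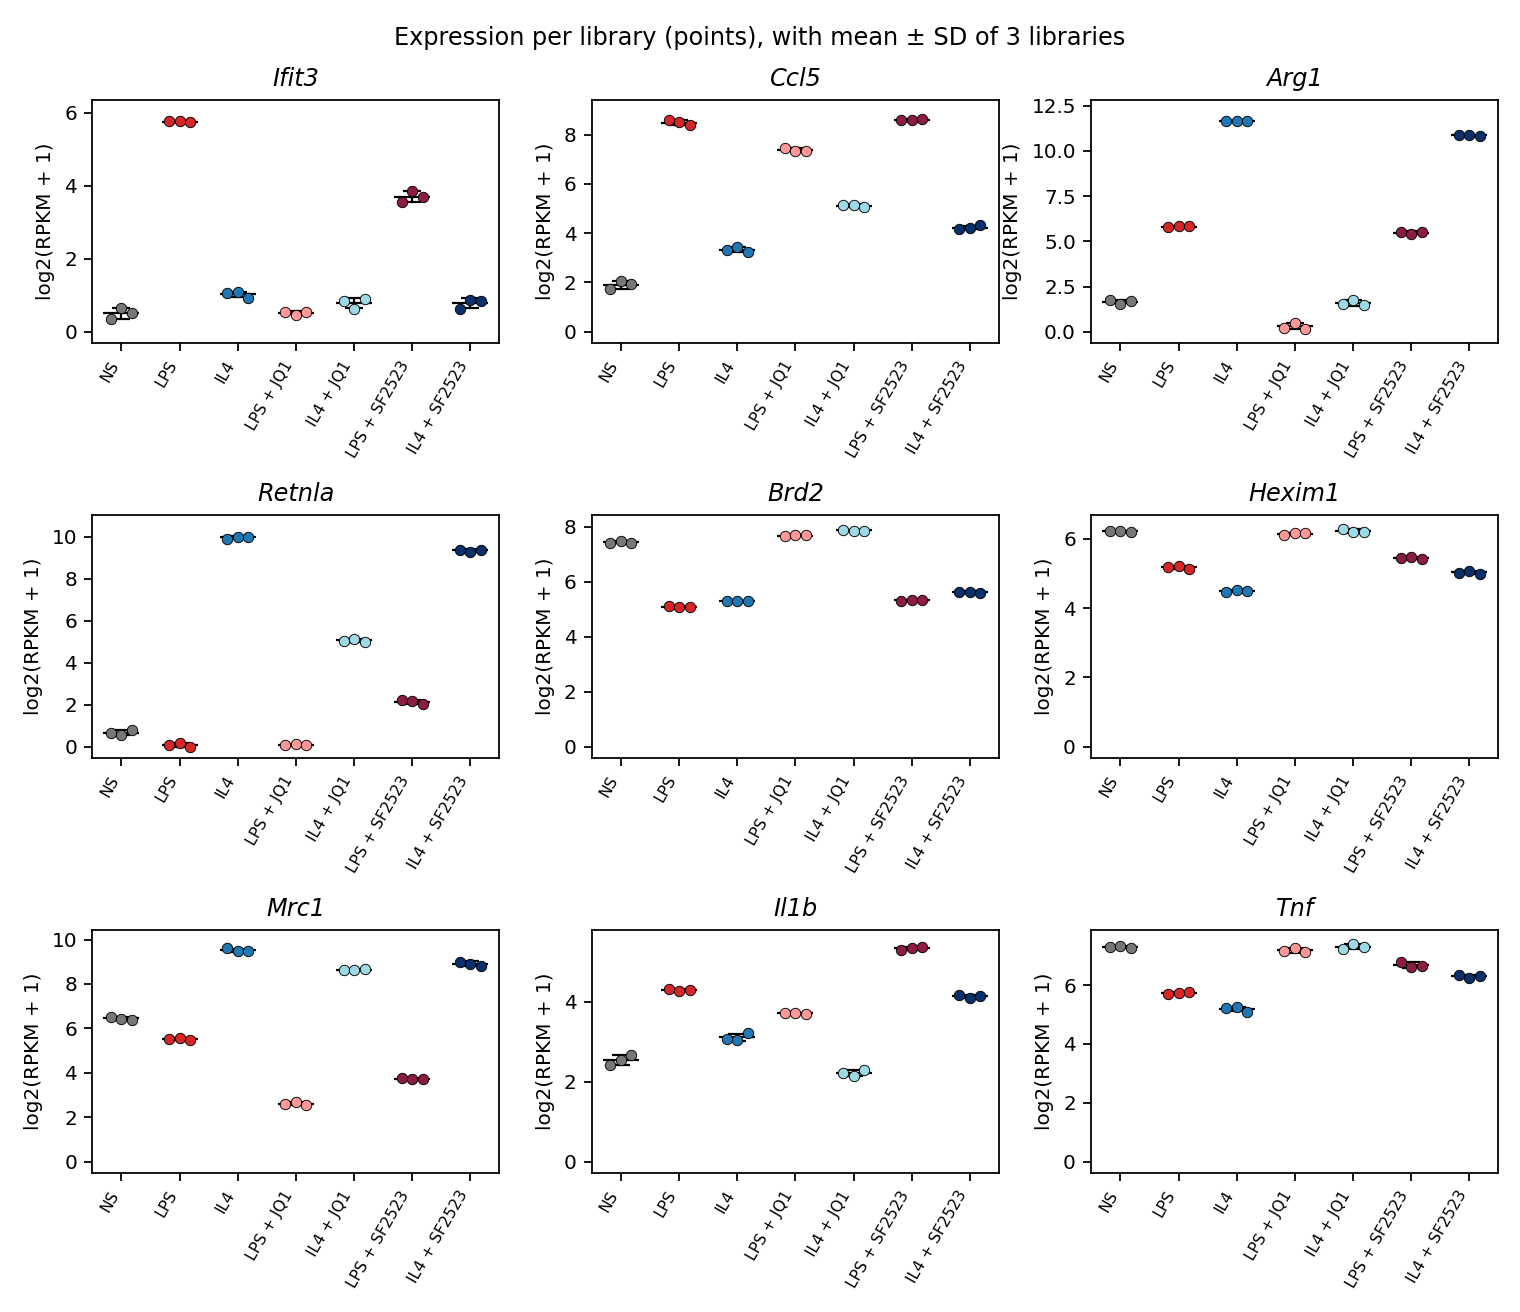
RPKM as log2(RPKM + 1) on the y axis for 9 genes in the 7 groups on the x axis. Points are the 3 libraries of each group, and the dash and bars are their mean ± SD; Arg1 reached 3182 ± 13.6 RPKM with IL4 and 2.01 ± 0.306 with IL4 and JQ1.

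Whether BET inhibition changes the response to LPS was asked by comparing LPS with JQ1 to LPS alone. Of the 5238 genes higher with LPS than in NS, 4638 were lower with JQ1 added (88.5%, where independent lists would share 2558). Because the NS libraries lay near the JQ1 libraries, this overlap largely follows from their position. All 33 interferon genes fell, with a median of -2.71 (limma camera adjusted p = 6.15e-15). Ifit3 fell from 53.3 ± 0.873 to 0.43 ± 0.0422 RPKM, Siglec1 from 135 ± 2.42 to 2.28 ± 0.0392 (log2 -5.37 ± 0.03, limma adjusted p = 8.08e-26), and Isg15 at -4.16 on the log2 scale. The monocyte chemokine Ccl12 (ENSMUSG00000035352, GRCm38 chromosome 11, 82101845 to 82103400) fell from 150.0 ± 1.88 to 2.12 ± 0.704 RPKM and Arg1 from 55.3 ± 1.15 to 0.235 ± 0.151. Mrc1 fell from 45.2 ± 1.07 to 5.12 ± 0.28.

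Fc receptors and coagulation factor F13a1 fell with them, Fcgr1 at -5.03, Fcgr4 at -3.63 and F13a1 at -4.74 on the log2 scale. The complement, scavenger and Fc receptor list had 2 members higher and 12 lower of 15 (camera adjusted p = 0.00681). All 29 proliferation genes fell (median -1.7, camera adjusted p = 1.68e-12), with the mitotic kinase Aurkb at -1.98 and Mcm5 at -1.93. All 19 sterol synthesis genes fell (median -0.83, 2.04e-05), with Dhcr24 at -1.60 and Cyp51 at -1.42. MYC targets had 2 higher and 16 lower of 18 (camera adjusted p = 0.0139), and Myc fell by 0.41. MHC class I genes had 2 higher and 9 lower of 12 (0.0429, and adjusted p = 0.295 with an estimated correlation by camera), with the immunoproteasome subunit Psmb10 at -2.04. Single genes of interest fell as well: Il10 at -1.81, Cd274 at -0.96, Nos2, the inducible nitric oxide synthase, at -0.99, Il1b at -0.58 and Il6 at -0.56. Inflammatory cytokines had 4 higher and 16 lower of 20 (camera adjusted p = 0.0844, and 0.0272 with median-ratio scaling), and tumour-promoting genes 3 higher and 9 lower of 15 (0.0894, and 0.0352 with median-ratio scaling). Tnf and Cxcl2 were among the exceptions and rose, Tnf from 52.2 ± 0.756 to 144 ± 7.19 RPKM and Cxcl2 by 1.34.

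Genes that BET inhibitors are known to raise rose. All 7 listed ones did, with a median of 1.94 (camera adjusted p = 9.93e-07), Hist1h1c from 4.9 ± 0.338 to 106 ± 3.07 RPKM, Brd2 from 33.3 ± 0.661 to 205 ± 1.97 and Hexim1 from 35.4 ± 1.11 to 69.9 ± 1.15. NF-kB feedback genes had 15 higher and 1 lower of 16 (median 0.76, 2.87e-08), Nfkbie by 1.52 and Tnip3 by 1.32. Immediate early genes had 10 higher and 1 lower of 11 (camera adjusted p = 5.3e-06), with Nr4a1 at 3.14 and Dusp2 at 2.70. FOXO targets had 10 higher and 2 lower of 13 (0.000512, and adjusted p = 0.067 with an estimated correlation by camera), Txnip at 1.80. Lysosomal genes had 12 higher and 4 lower of 20 (0.00377 by camera). Cd74, the MHC class II invariant chain, rose from 32 ± 0.601 to 352 ± 4.81 RPKM, the oxidative stress gene Nqo1 by 3.45, and the metallothioneins Mt1 by 3.12 and Mt2 by 3.63.

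The STAT6 list had 7 higher, 10 lower and 8 not called. Neutrophil markers had 3 higher and 6 lower (camera adjusted p = 0.346), and all 4 osteoclast markers fell (0.0341, and adjusted p = 0.15 with an estimated correlation by camera). In total 3280 genes were higher and 5427 lower by limma, 308 and 1093 of them by at least 2-fold, and list counts adjusted over the list alone were the same for every list. The median of all genes was -0.117, and scaling moved the split to 4445 higher and 4331 lower with median ratios (median 0.014), 4924 and 4039 with quantiles and 4319 and 4414 with the length trend removed. Without LPS replicate 3 the counts were 3262 and 5231, and with the NS libraries out of the fit 3322 and 5455. The highest limma adjusted p of a gene named here was 2.02e-06.

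The same question was asked for IL4. Of the 6034 genes higher with IL4 than in NS, 5289 were lower with JQ1 added (87.7%, where independent lists would share 3084). This overlap, too, largely follows from the position of NS near the JQ1 libraries. Of the 25 STAT6 genes 22 fell and 2 rose, with a median of -2.01 (limma camera adjusted p = 9.42e-07). Arg1 fell from 3182 ± 13.6 to 2.01 ± 0.306 RPKM (log2 -10.05 ± 0.07, limma adjusted p = 1.13e-23), Mgl2 from 778 ± 2.13 to 5.87 ± 0.621 and Retnla from 1005 ± 39.4 to 32.4 ± 1.72. Chil3 (from 1426 ± 58.2 to 354 ± 15.7 RPKM) and Mrc1 (from 736 ± 33.6 to 400.1 ± 9.28) also fell.

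Rnase2a fell by 8.53 on the log2 scale, Mmp12 at -6.15, the vacuolar ATPase subunit Atp6v0d2 at -5.62, Ccl8 at -5.21, Ccl12 at -5.30 and the IL7 receptor Il7r at -3.90. MHC class II members were divided, with 3 higher, 7 lower and 1 not called (camera adjusted p = 0.348). H2-Aa (-4.08), H2-Eb1 (-4.24) and H2-Ab1 (-3.73) fell, whereas Cd74 rose by 1.54. MYC targets had 16 lower and none higher of 18, or 17 lower when adjusted over the list alone (median -1.09, camera adjusted p = 1.76e-05), and Myc fell from 40.2 ± 0.94 to 12.2 ± 0.252 RPKM. All 29 proliferation genes fell (median -1.06, 2.74e-08), with Mcm2 at -1.65. Integrated stress response genes had 2 higher and 9 lower (camera adjusted p = 0.0906, and 0.0466 with median-ratio scaling), Psat1 at -2.34 and Asns at -2.45.

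Rising genes again included all 7 of the BET inhibitor list (median 1.79, camera adjusted p = 3.64e-06), with Brd2 from 38.6 ± 0.304 to 234 ± 4.13 RPKM and Hexim1 from 21.6 ± 0.427 to 73.8 ± 3.11. FOXO targets had 11 higher and 1 lower of 13 (4.97e-06), led by Klf2 (from 6.04 ± 0.267 to 94.1 ± 7.56 RPKM). NF-kB feedback genes had 13 higher and 3 lower of 16 (3.64e-06), with Nfkbia at 1.88 and Nfkbie at 1.53. Immediate early genes had 9 higher and 2 lower of 11 (0.0011 by camera). Tnf rose from 35.5 ± 1.98 to 158 ± 9.05 RPKM, Cxcl1 by 1.92 and complement C3 by 2.54, while Il1b fell by 0.90. MHC class I genes had 6 higher, 3 lower and 3 not called (camera adjusted p = 0.0385, and adjusted p = 0.33 with an estimated correlation), with H2-K1 at 1.44 and H2-D1 at 1.39. The nuclear noncoding RNA Malat1 rose by 2.72.

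Interferon genes were divided, with 13 higher, 12 lower and 8 not called (camera adjusted p = 0.288), and their median of -0.02 changed sign with scaling. Lysosomal genes had 10 higher and 7 lower, with a median of 0.07, a mean of -0.1 and an upward test (0.0446, and adjusted p = 0.173 with an estimated correlation by camera). Sterol genes had 3 higher and 12 lower (0.356 by camera), neutrophil markers 5 and 4 (0.294), and all 4 osteoclast markers fell (camera adjusted p = 0.00366, 0.0497 with an estimated correlation). Limma called 3229 genes higher and 5679 lower, 329 and 1101 by at least 2-fold, with a median of -0.158 over all genes. Scaling by median ratio (median 0.006) gave 4522 and 4367, quantiles 4859 and 4126, and removal of the length trend 4450 and 4397. With the NS libraries out of the fit the counts were 3257 and 5713. All IL4 with JQ1 libraries carried the title letter B and all IL4 ones A. The highest limma adjusted p of a gene named here was 1.73e-11.

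LPS with SF2523 was compared with LPS to ask what the dual inhibitor does to the same response. Interferon and sterol genes were lower with SF2523. All 33 interferon genes fell, with a median of -1.21 (limma camera adjusted p = 1.43e-13), and 17 of 19 sterol synthesis genes fell with none higher (median -0.7, 3.65e-05). Ifit2 fell from 34.1 ± 0.71 to 4.18 ± 0.455 RPKM (log2 -2.76 ± 0.09, limma adjusted p = 3.48e-14), the antiviral gene Rsad2 from 27.4 ± 1.24 to 4.11 ± 0.293 and Ifit3 from 53.3 ± 0.873 to 12.1 ± 1.26. The LDL receptor Ldlr fell by 0.85 on the log2 scale, Insig1 at -1.04, the rate-limiting enzyme of cholesterol synthesis Hmgcr at -0.94, and the fatty acid desaturase Scd2 from 82.2 ± 4.58 to 15.7 ± 0.787 RPKM.

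The largest fall was that of Ccl12, from 150.0 ± 1.88 to 18 ± 0.947 RPKM, and the IL1 receptor antagonist Il1rn fell from 11.6 ± 0.469 to 1.49 ± 0.0294. Mrc1 fell from 45.2 ± 1.07 to 12.2 ± 0.341, Ccl7 at -1.54 on the log2 scale, Ccl2 at -0.89, Cd274 at -0.88 and Nos2 at -0.83. Arg1 fell by 0.33, a call that ended with a pseudocount of 0.1 (limma adjusted p = 0.113). In the other direction Il1b rose from 18.5 ± 0.205 to 39.3 ± 0.865 RPKM, Tnf from 52.2 ± 0.756 to 102 ± 6.51, the LPS co-receptor Cd14 from 254 ± 12.1 to 587 ± 19.4 and the gelatinase Mmp9 from 213 ± 12 to 431 ± 3.56. Cx3cr1 (ENSMUSG00000052336, GRCm38 chromosome 9, 119901616 to 120069879), the fractalkine receptor, rose from 6 ± 0.0762 to 20.7 ± 0.354 RPKM, and the granulocyte growth factor Csf3 from 5.79 ± 0.415 to 18.6 ± 1.27. Inflammatory cytokines were thus divided, with 7 higher, 7 lower and 6 not called (camera adjusted p = 0.459). Il6 (0.646 ± 0.0367 RPKM with SF2523, 0.639 ± 0.0322 without) and Il10 (6.78 ± 0.734 and 6.84 ± 0.79) were not called, though Il6 passed with quantile normalization (limma adjusted p = 0.032).

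NF-kB feedback genes had 13 higher and 2 lower of 16 (median 0.51, camera adjusted p = 2.4e-05), with Relb at 0.75 and Tnip1 at 0.72. Macrophage identity genes had 15 higher and 4 lower of 19 (median 0.4, 4.21e-05). The BET inhibitor list had 5 higher and none lower of 7, or 6 higher when adjusted over the list alone (median 0.28, 0.000906), with Hist1h1c at 1.23, Brd2 from 33.3 ± 0.661 to 39.3 ± 0.633 RPKM and Hexim1 from 35.4 ± 1.11 to 43 ± 0.809. The call of Brd2 ended when libraries were rescaled to a common RPKM sum (log2 0.05, limma adjusted p = 0.136). Immediate early genes had 6 higher, none lower and 5 not called (0.000989), Fos at 0.83 and Ier2 at 0.93. MHC class II genes had 6 higher, 1 lower and 4 not called (0.00947), with a median of 0.16 that became -0.01 when libraries were rescaled to a common RPKM sum. These p-values are limma camera adjusted p. Neutrophil and precursor markers had 7 higher and none lower of 9, or 8 higher when adjusted over the list alone (7.71e-05 by camera). Myc rose by 0.51. FOXO targets, which are known to rise under PI3K inhibitors, had 2 higher, or 3 when adjusted over the list alone, and 10 lower of 13 (camera adjusted p = 0.459), with a median of -0.23 that changed sign with the length trend removed. Proliferation genes had 7 higher and 20 lower (0.518 by camera), MYC targets 4 and 8 (0.995), lysosomal genes 4 and 14 (0.108), tumour-promoting genes 3 and 9 (0.352), STAT6 genes 9 and 8 (0.164) and osteoclast markers 1 and 1. Mgl2 (from 0.132 ± 0.00803 to 4.37 ± 0.315 RPKM) and Retnla (from 0.0596 ± 0.0596 to 3.38 ± 0.3) rose from levels near the floor.

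Limma called 2951 genes higher and 5207 lower, 59 and 225 of them by at least 2-fold. The counts at 2-fold were 46 and 835 with rescaling to a common RPKM sum, 124 and 632 with a pseudocount of 0.1, 145 and 719 with voom and 104 and 155 with median ratios. Rescaling also changed the number of tested genes to 13517 and gave the pseudocount less weight. The split moved widely with scaling, to 1643 higher and 7575 lower when libraries were rescaled to a common RPKM sum (median of all genes -0.275, against -0.099), 4117 and 4071 with median ratios (median 0.005), 4151 and 3989 with quantiles and 3791 and 3806 with the length trend removed. Fold changes also followed exon length, with a Spearman's rho across genes of -0.465 and medians of 0.18 in the shortest of 5 equal bins of genes and -0.35 in the longest. All SF2523 libraries carried the title letter B and all drug-free ones A. Without LPS replicate 3 limma called 2882 and 4953, and with the NS libraries out of the fit 2972 and 5238. The highest limma adjusted p of a changed gene named here was 0.000622.

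With IL4, 47 genes were higher and 100 lower with SF2523 by at least 2-fold. These counts were 45 and 297 with rescaling to a common RPKM sum, 88 and 254 with a pseudocount of 0.1 and 111 and 293 with voom. The NF-kB feedback list rose, with 14 members higher and 1 lower of 16 (median 0.49, limma camera adjusted p = 2.92e-07), and so did macrophage identity genes, with 14 higher and 3 lower of 19 (median 0.54, 1.99e-05). The STAT6 list fell moderately, with 16 members lower, 2 higher and 7 not called (median -0.38, 0.00223). Fpr1 (ENSMUSG00000045551, GRCm38 chromosome 17, 17876471 to 17883940) rose from 19.7 ± 0.19 to 104 ± 1.78 RPKM (log2 2.35 ± 0.03, limma adjusted p = 3.78e-20), and Il7r (ENSMUSG00000003882, GRCm38 chromosome 15, 9505788 to 9530176) fell from 14.6 ± 0.993 to 2.21 ± 0.247.

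Among the alternative activation genes, Arg1 fell from 3182 ± 13.6 to 1859 ± 49.2 RPKM, Retnla from 1005 ± 39.4 to 653 ± 25.3, Mrc1 at -0.61 on the log2 scale and Chil3 at -0.39. Pparg, a nuclear receptor of lipid metabolism, fell from 11.6 ± 0.23 to 3.18 ± 0.245 RPKM, with the fatty acid carriers Fabp4 at -1.90 and Cd36 at -1.29. All 4 osteoclast markers fell (median -0.75, camera adjusted p = 0.00098), with the collagen-degrading protease Ctsk at -1.92. Atp6v0d2, which is not on that list, was at -1.89. Integrated stress response genes had 1 higher and 11 lower of 13 (median -0.66, camera adjusted p = 0.00031), Psat1 at -0.81 and Mthfd2 at -0.66.

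Inflammatory cytokines and chemokines were divided, with 10 higher, 7 lower and 3 not called (camera adjusted p = 0.477), and their median of 0.08 became -0.04 with rescaling to a common RPKM sum. Tnf rose from 35.5 ± 1.98 to 77.9 ± 2.12 RPKM and Il1b from 7.63 ± 0.518 to 16.5 ± 0.51, whereas Ccl2 (-0.89 on the log2 scale), Ccl7 (-0.93), Ccl8 (-1.02) and Ccl12 (-1.50) fell, the last 3 chosen after their values were seen. Mmp9 rose from 76.4 ± 1.55 to 252 ± 5.01 RPKM and Fpr2 from 16.6 ± 0.947 to 59.1 ± 0.208. Relb rose by 1.04, Nfkbie by 1.16, Cd14 by 1.16, Adgre1 by 0.73 and Klf2 by 1.73. MHC class I genes had 10 higher and 2 lower of 12 (0.00223, and adjusted p = 0.165 with an estimated correlation by camera). The BET inhibitor list had 4 higher and none lower of 7 (0.0169, and adjusted p = 0.0772 with an estimated correlation by camera), with Hexim1 from 21.6 ± 0.427 to 31.7 ± 0.958 RPKM and Brd2 from 38.6 ± 0.304 to 48.3 ± 1.07. Myc was not called, at 41 ± 0.342 RPKM with SF2523 and 40.2 ± 0.94 without. MYC targets had 1 higher, 10 lower and 7 not called, or 11 lower when adjusted over the list alone (camera adjusted p = 0.0543). Neutrophil markers had 5 higher and none lower of 9 (0.00411). Camera did not set apart proliferation genes (7 higher, 14 lower, adjusted p = 0.92), interferon genes (6 and 16, 0.499), sterol genes (4 and 7, 0.993), FOXO targets (5 and 7, 0.92) or MHC class II genes (4 and 6, or 5 higher when adjusted over the list alone, 0.993, with a median that changes sign with scaling).

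Limma called 3134 genes higher and 4018 lower in all. Rescaling to a common RPKM sum moved the split to 1915 and 5676 (median of all genes -0.132, against -0.027). Other settings turned the majority to higher: 3592 and 3491 with median ratios, 3577 and 3468 with quantiles and 3481 and 3269 with the length trend removed. Fold changes followed exon length across genes here too, with a Spearman's rho of -0.395. With the NS libraries out of the fit the counts were 3148 and 4068, and without IL4 with SF2523 replicate 3 (array weight 0.446) 2781 and 3597. The highest limma adjusted p of a changed gene named here was 1.26e-06.

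**Figure D3:**
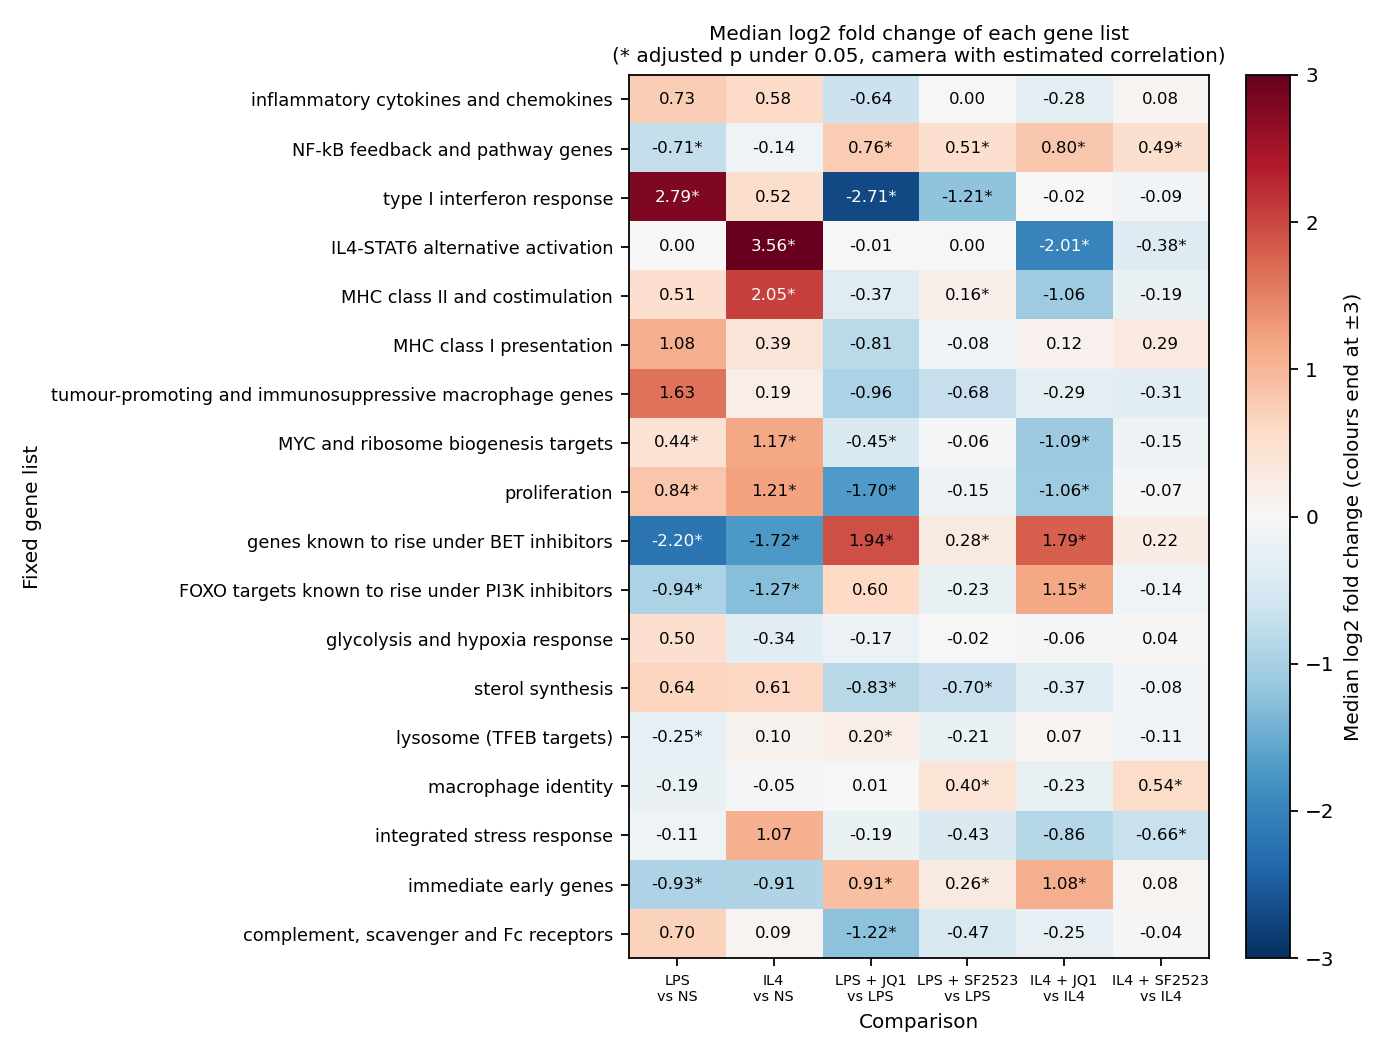
Median log2 fold change of each of the 18 gene lists (y axis) in the 6 comparisons with a drug-free or NS reference (x axis), as colour. A star marks a camera adjusted p under 0.05 with an estimated correlation; interferon genes had a median of 2.79 with LPS, -2.71 with JQ1 added and -1.21 with SF2523 added.

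The inhibitors were compared directly within each stimulus, at doses the labels do not give. With LPS, interferon and proliferation genes were higher with SF2523 than with JQ1, all 33 (median 1.27, limma camera adjusted p = 6.16e-11) and all 29 (median 1.6, 6.47e-13). Arg1 was at 43.8 ± 2.14 RPKM with SF2523 and 0.235 ± 0.151 with JQ1 (log2 5.19 ± 0.07). Clec4a1 differed by 5.36 on the log2 scale, Fcgr1 by 4.51, Isg15 by 2.90, Il1b by 1.62 and Myc by 0.92. All 7 BET inhibitor genes were lower with SF2523 (median -1.67, camera adjusted p = 0.000137). Brd2 was at 39.3 ± 0.633 RPKM with SF2523 and 205 ± 1.97 with JQ1, Hist1h1c differed by -2.96, Hexim1 by -0.69 and Nr4a1 by -3.02. Lysosomal genes had 4 higher and 16 lower (0.000774), immediate early genes 1 and 10 (0.00431) and neutrophil markers 9 and 0 (0.00039) by camera. Calls that ended with an estimated correlation were those of FOXO targets (1 higher, 11 lower, adjusted p = 0.0852 with an estimated correlation), NF-kB feedback genes (2 and 11, 0.113), MYC targets (11 and 2, 0.0632), complement and scavenger receptors (11 and 3, 0.0712), macrophage identity (13 and 4, 0.255) and osteoclast markers (4 and 0, 0.0571), by camera. Limma called 4852 genes higher and 4174 lower, 860 and 460 by at least 2-fold. Rescaling to a common sum, which moved the median of all genes from 0.051 to -0.097, gave 4149 and 5722, and 957 and 1205 at 2-fold. Quantile normalization gave 4249 and 4717, median ratios 4677 and 4356, and removal of the length trend 4466 and 4343.

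With IL4, 20 of 25 STAT6 genes were higher with SF2523 than with JQ1 and 1 was lower (median 1.55, limma camera adjusted p = 1.34e-05). Arg1 was at 1859 ± 49.2 RPKM with SF2523 and 2.01 ± 0.306 with JQ1 (log2 9.27 ± 0.07), Mgl2 differed by 6.83 and Retnla by 4.29. Also higher were 17 of 18 MYC targets (camera adjusted p = 0.000252), all 29 proliferation genes (7.45e-08) and H2-Ab1, by 3.17. Lower with SF2523 were all 7 BET inhibitor genes (median -1.54, camera adjusted p = 3.01e-05), 12 of 13 FOXO targets (1.29e-05), 14 of 20 lysosomal genes (0.00149) and 9 of 11 immediate early genes (0.00507). Brd2 was at 48.3 ± 1.07 RPKM with SF2523 and 234 ± 4.13 with JQ1, Hexim1 differed by -1.19 and Malat1 by -3.12. NF-kB feedback genes had 4 higher and 11 lower (0.00986, and adjusted p = 0.164 with an estimated correlation by camera), and all 4 osteoclast markers were higher (0.00933, and adjusted p = 0.0774 with an estimated correlation by camera). Limma called 5569 genes higher and 3567 lower, 1009 and 373 by at least 2-fold. The counts at 2-fold were 1250 and 835 with rescaling to a common RPKM sum and 675 and 588 with quantiles. Median-ratio scaling, which moved the median of all genes from 0.138 to 0.011, gave 4602 and 4468, quantiles 4344 and 4747, and removal of the length trend 4534 and 4383.

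Whether the inhibitors acted on the same genes was examined by overlap of calls within a stimulus. With LPS, 129 of the 225 genes that SF2523 lowered at least 2-fold were also lowered at least 2-fold by JQ1 (57.3%), where independent lists would share 22.1, and 23 of the 59 it raised were also raised (39%, against 1.64). With IL4 the shared falls were 75 of 100 (75%, against 9.91) and the shared rises 20 of 47 (42.6%, against 1.39). These overlaps at 2-fold were counted with the reported scaling and pseudocount only. At any fold, 2987 genes fell with both inhibitors under LPS and 1240 rose with both, where independent lists would share 2543 and 871, while 1229 and 1119 went opposite ways (1537 and 1441). Under IL4, 2312 fell and 1205 rose with both (2053 and 911), and 1037 and 1377 went opposite ways (1168 and 1602). Across genes, which are not independent replicates, the fold changes of JQ1 and SF2523 correlated at r = 0.337 with LPS and 0.291 with IL4. Shared controls alone gave 0.492 and 0.495 in simulation, but from noise in groups without change, so those values are no baseline for r here. The covariance of the fold changes was 0.102 and 0.0717 against a simulated 0.00381 and 0.00384, a difference of 0.0982 and 0.0679. Median-ratio scaling moved the counts shared under LPS to 1956 falls and 2049 rises. It also changed the calls, to 4331 lower and 4445 higher with JQ1 and 4071 lower and 4117 higher with SF2523, of 11080 tested. The values given above for independent lists therefore do not apply to it. Noise between the shared control libraries thus gave only a small part of the covariance. The simulation holds no difference common to all 3 controls of a stimulus. The controls were not split between the inhibitors, so part of the excess overlap may come from such a difference.

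**Figure D4:**
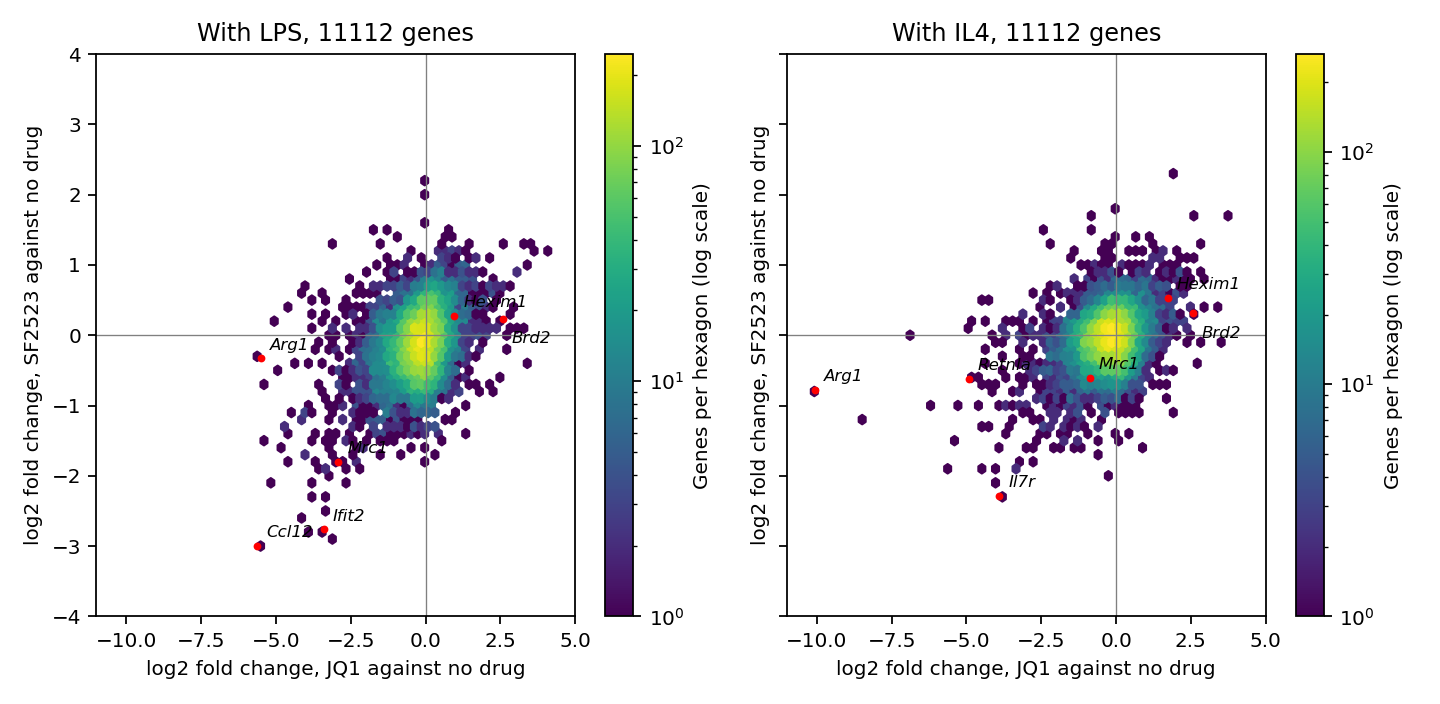
Log2 fold change with JQ1 (x axis) against that with SF2523 (y axis) over the 11112 tested genes, for LPS and for IL4, as hexagons coloured by number of genes. Pearson's r across genes was 0.337 with LPS and 0.291 with IL4, and the named genes are labelled at their values.

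Stimulus-induced genes were then followed under each inhibitor. Of the 1008 genes LPS raised at least 2-fold over NS (median 1.4), JQ1 lowered 989 (98.1%, median -1.34) and SF2523 lowered 612 (60.7%, median -0.29). Of the 1324 that IL4 raised (median 1.37), JQ1 lowered 1287 (97.2%, median -1.21) and SF2523 674 (50.9%, median -0.14). Among all 11112 tested genes SF2523 lowered 5207 with LPS and 4018 with IL4 and raised 2951 and 3134, so part of its shares is background. JQ1 lowered 5427 and 5679 of all tested genes and raised 3280 and 3229. With median ratios SF2523 lowered 4071 genes with LPS and 3491 with IL4. Genes that fell at least 2-fold with the stimulus were raised by JQ1 in 95.8% of 310 cases for LPS and 96.2% of 397 for IL4, and by SF2523 in 56.1% and 59.4%. The JQ1 shares largely follow from the position of NS near the JQ1 libraries (median 0.955). They are no separate support for a block of the response by JQ1. The stimulus and inhibitor comparisons also share the drug-free libraries as control and as treated group, which alone drives their fold changes apart. Across genes, r was -0.899 between LPS vs NS and LPS with JQ1 vs LPS, where unchanged groups gave -0.502, with a covariance of -0.471 against -0.00387. For IL4 it was -0.909 against -0.504. For SF2523 it was -0.28 against -0.503 with LPS and -0.296 against -0.494 with IL4. The simulated r comes from noise in groups without change, so it is no baseline for r where fold changes spread more widely. The covariances for SF2523 were -0.0853 against -0.00391 and -0.0802 against -0.00385, larger in size than shared libraries alone gave. Because NS lay near the JQ1 libraries, they may largely repeat the covariances of JQ1 with SF2523 (0.102 and 0.0717). The same holds for the SF2523 shares, so neither is separate support that SF2523 opposes the response to the stimulus.

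Finally, each inhibitor's effect was tested for a difference between stimuli, as its effect with LPS minus its effect with IL4. The effect of JQ1 on interferon genes was lower with LPS for all 33 (median -2.64, limma camera adjusted p = 2.45e-35), led by Ifit2 at -5.03 and Ifit3 at -5.00. On STAT6 genes it was higher with LPS for 22 of 25, or 23 when adjusted over the list alone, and lower for 2 (median 1.96, 9.6e-15), led by Rnase2a at 8.47, Mgl2 at 6.74 and Retnla at 4.90. Rnase2a and Mgl2 were at 0.104 ± 0.0896 and 0.132 ± 0.00803 RPKM with LPS alone and Ifit3 at 1.04 ± 0.107 with IL4 alone, so a fall there was bounded by the low level. The same limit may hold for other members, since interferon genes had a median of 0.52 in IL4 vs NS and STAT6 genes 0 in LPS vs NS. Ifit2 rose with JQ1 under IL4, from 2.85 ± 0.383 to 10.8 ± 0.439 RPKM, and so part of its difference is a change in the opposite direction, as it is for Gbp2, Rsad2 and Cmpk2, these 3 chosen after their values were seen. The effect was lower with LPS for all 29 proliferation genes (median -0.69, camera adjusted p = 9.6e-15), all 12 MHC class I genes (1.02e-09) and 18 of 19 sterol genes (median -0.55, 6.05e-08), and higher for all 18 MYC targets (median 0.61, 9.47e-09). Limma called 6034 genes, 3325 with a higher effect with LPS and 2709 with a lower one, a majority that turned with median-ratio scaling (2865 and 3078) and with the length trend removed (2917 and 3062). In all 2348 genes rose with JQ1 under both stimuli, 4507 fell under both and 694 went opposite ways (r = 0.692 across genes).

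For SF2523 the effect was lower with LPS for 32 of 33 interferon genes, or 33 when adjusted over the list alone (median -1.22, limma camera adjusted p = 2.79e-30), with Ifit2 at -2.27, and for all 19 sterol genes (median -0.63, 6.04e-12). Outside these lists Slfn4 was at -2.41. With IL4 alone Ifit2 and Slfn4 were at 2.85 ± 0.383 and 0.5095 ± 0.0484 RPKM, which bounded a fall there too. It was higher with LPS for 16 of 25 STAT6 genes, or 17 when adjusted over the list alone (median 0.45, camera adjusted p = 1.08e-10), and for all 4 osteoclast markers (2e-07). Retnla at 2.67 and Mgl2 at 2.25 led these. Limma called 1080 genes with a higher and 2788 with a lower effect with LPS, 3868 in all. That split became 729 and 3708 after rescaling to a common sum (median of all genes -0.142, against -0.07), 1767 and 1731 with median ratios, 1754 and 1911 with quantiles and 1536 and 1605 with the length trend removed. Under both stimuli 2220 genes rose with SF2523 and 3557 fell, and 332 went opposite ways (r = 0.715 across genes).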

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

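The tests of the 3 patterns weighed here were chosen only after the results were seen, whereas the counts over other splits of the libraries were planned before.

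Each drug's effect differed between the stimuli by a test of the difference itself. For JQ1 6034 genes differed, with median differences (LPS minus IL4, log2) of -2.64 for interferon genes, 1.96 for STAT6 genes and -0.55 for sterol genes. For SF2523 3868 genes differed, with medians of -1.22, 0.45 and -0.63 for the same lists. Interferon genes had a median of 2.79 in LPS vs NS and 0.52 in IL4 vs NS, and STAT6 genes 0 and 3.56. Under the stimulus that did not raise a list, a fall is bounded by low levels. The differences of the interferon and STAT6 lists may therefore reflect which stimulus raised them. Sterol genes had medians of 0.64 in LPS vs NS and 0.61 in IL4 vs NS. For SF2523, the ratios seen with LPS would give medians of -0.818 for interferon and -0.744 for sterol genes from the IL4 levels. With IL4 the medians were -0.095 and -0.082, which argues against low levels as the whole cause of the SF2523 differences of those lists. JQ1 gave interferon genes -2.71 with LPS and -0.02 with IL4, and STAT6 genes -0.01 and -2.01. Of 100 splits of the libraries within each stimulus, the real one included, 10 gave as many genes for JQ1 (highest other 9391) and 8 for SF2523 (highest other 8643), so this count does not exclude chance. It does not speak for chance either: in each of the other 9 and 7 the numbers of libraries with exchanged drug labels differed by at least 2 between the stimuli, as was seen after the counts, which brings the drug's own effect into the difference. The 48 splits that exchanged equal numbers called at most 0 genes for JQ1 and 1 for SF2523, but they also mix drug and drug-free libraries within groups, which widens the spread. The JQ1 difference also follows the A and B title codes, since IL4 with JQ1 is B and the 3 other groups in it are A.

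The comparisons of 3 against 3 libraries have 10 splits each, too few for a share under 0.05. Limma called 8593 genes for LPS vs NS, 9038 for IL4 vs NS, 8707 for LPS with JQ1 vs LPS, 8908 for IL4 with JQ1 vs IL4, 7152 for IL4 with SF2523 vs IL4, and 9026 and 9136 for SF2523 vs JQ1 with LPS and IL4, with a highest other split of 0 genes in each. For LPS with SF2523 vs LPS it called 8158, with a highest other of 1. In each of these 8 comparisons 1 of the 10 splits, the real one, gave as many. The other splits mix libraries of both groups, which widens the spread and shrinks the difference, so their low counts are no support for the calls.

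The libraries labelled NS lay near the JQ1 libraries. Scaling was argued against, since the median position of NS between the drug-free (0) and JQ1 (1) means stayed at 0.959 with median-ratio scaling. A hypothesis that these cells had been exposed to JQ1, or carry a wrong label, may hold: it needs a position near 1, and the value was 0.955 over genes chosen without the NS libraries. A biological alternative is that JQ1 keeps genes at the level they had without LPS or IL4. Both stimulus comparisons called 98% of those genes the other way, but that follows from the position of NS and is no separate support. Genes known to rise under BET inhibitors, a list written before the data were examined, held the same position. Their median log2 fold change was -2.2 in LPS vs NS and 1.94 with JQ1 added, and -1.72 and 1.79 for IL4. Exposure to JQ1 would raise them in NS, while the alternative needs both stimuli to lower them. Of the 759 genes that JQ1 moved under both stimuli, 7 (0.92%) had an NS position under 0.25 and 666 (87.7%) one over 0.75. Over the 317 of them about level between the stimuli, with and without JQ1, the median was 0.96. The alternative allows this only if both stimuli moved nearly all of these genes, the level ones by similar amounts. The 2 explanations cannot be told apart, because that was not excluded and no group is labelled as JQ1 without LPS or IL4.

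Interferon and sterol genes were lower when SF2523 was added to LPS. A trend on transcript length, which SF2523 showed, was argued against as the whole cause: with it removed, the medians were -1.117 for interferon and -0.516 for sterol genes. Scaling was argued against in the same way (-1.095 and -0.612 with median ratios), as was foreign RNA in LPS replicate 3 (without it the sterol list, the smaller change, had a median of -0.709). A shift shared by all libraries with title letter B was argued against as the whole cause. IL4 with SF2523 vs IL4 parts the same letters, and its medians were -0.095 for interferon and -0.082 for sterol genes, where the ratios seen with LPS would give -0.818 and -0.744 from the IL4 levels. A difference in handling of the LPS libraries alone stays open, and an effect of the drug, which the design names, remains a hypothesis.

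LPS replicate 3 held transcripts that the other libraries lacked. There were 57 genes at RPKM 1 or more there and at most 0.1 elsewhere, among them Ly6c1 (9.98 RPKM), Ces1f (6.09), Aqp5 (4.11) and Krt8 (3.24), chosen after their values were seen. A response to LPS that the LPS libraries share could not be tested by this count. The rule kept only genes at most 0.1 RPKM in every other library, LPS replicates 1 and 2 included. Replicates 1 and 2, each counted against its other 20 libraries, held at most 0 such genes. A gene that the LPS libraries share could not have counted for either, so no conclusion is drawn from that value. RNA from cells of another kind stays open, since the count is the pattern itself and does not test a source, and so does a response in that library alone. Mesothelial cells stay open as a source. Of 8 markers listed before their values were seen 5 were at or under 0.1 RPKM there, but Krt19 of that list (1.25 RPKM) and Msln (19.5), Krt8 and Krt18 (6), added to it after their values were seen, were above 0.5 RPKM and 5 times the other LPS libraries. No marker of the epithelial, endothelial or bone lineage lists was. Of the 7 markers of the planned fibroblast list Sparc was (14.8 RPKM, against 0.851 and 0.8), and Col1a1 (3.43, against 0.617 and 0.712) and Col3a1 (1.64, against 0.379 and 0.349) were higher by less, while Col1a2, Dcn and Lum were at 0.348, 0.119 and 0.674, against 0.343 and 0.411, 0.147 and 0.116, and 0.541 and 0.554. Krt8, Krt18 and Krt19 were placed on the mesothelial list only, so these lists do not decide between mesothelial and epithelial cells. The kind of cell stays open.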

How the results depend on the processing

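Voom on the recovered reads, removal of the exon-length trend and the fit without the NS libraries were chosen only after the results were seen, and all other alternatives were planned. No paired analysis was possible because the labels give no replicate numbers. Of 800 medians of gene and marker lists under 4 scalings, 43 changed sign. Of the 452 from lists that camera called, 2 did, both with rescaling to a common RPKM sum: MHC class II in LPS with SF2523 vs LPS (0.16 to -0.01) and MYC targets in the SF2523 difference (0.06 to -0.01). Of 14320 values of the genes that the rule named, used in the text or not, 14237 kept their direction and side of the threshold, 16 moved past it, 44 fell short of it and 23 reversed. Of 540 values of list tests, 434 kept theirs, 79 passed the threshold and 27 no longer did, most of them with fry, which does not compare a list with other genes, or with an estimated correlation. Replicates were not left out for list tests. Depth limited low genes: at 20936387 to 51382355 reads per library, a gene of 1 kb with under 0.0584 to 0.143 RPKM held fewer than 3 reads.

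The 23 reversed values belong to genes that the text leaves out in those comparisons, after their values were seen, and the cause was not tested. As log2 fold changes, quantile normalization gave -0.051 for Ciita in LPS vs NS, -0.168 for Pik3cg in IL4 vs NS (-0.136 with median-ratio scaling), 0.131 for Retnla and 0.044 for Ciita in LPS with JQ1 vs LPS, and 0.037 for Il10 in IL4 with JQ1 vs IL4 (0.011 with the length trend removed). In LPS with SF2523 vs LPS, median-ratio scaling gave 0.007 for Chil3 and 0.016 for Pik3cg, and removal of the length trend gave 0.005 for Insr, 0.188 for Pik3cg, 0.011 for Pik3cd and 0.277 for Ciita. In IL4 with SF2523 vs IL4, removal of the length trend gave 0.019 for Brd4 and 0.049 for Pik3cg. For SF2523 vs JQ1 with LPS, rescaling to a common RPKM sum gave -0.083 for Cd274 and -0.041 for Pik3cd, quantile normalization -0.023 for Nos2, -0.021 for Cd274 and -0.06 for Pik3cd, and removal of the length trend -0.042 for Cd274. For SF2523 vs JQ1 with IL4, quantile normalization gave -0.233 and removal of the length trend -0.427 for Il10.

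Of 380 counts of higher or lower calls, 369 stayed within 1.5 times the reported count. Median-ratio scaling raised the lower calls of IL4 vs NS from 3004 to 4563 and changed the SF2523 difference between stimuli to 1767 higher and 1731 lower, from 1080 and 2788. Quantile normalization gave 4885 lower calls for IL4 vs NS, 4924 higher calls for LPS with JQ1 vs LPS (from 3280), 4859 higher calls for IL4 with JQ1 vs IL4 (from 3229) and 1754 higher calls for the SF2523 difference. Rescaling to a common RPKM sum reduced the higher calls of LPS with SF2523 vs LPS from 2951 to 1643 and of IL4 with SF2523 vs IL4 from 3134 to 1915. Array weights gave 1688 higher calls and removal of the length trend 1605 lower calls for the SF2523 difference. The cause was not tested.

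With 1 library left out, higher and lower calls ranged over 5057 to 5266 and 3145 to 3315 for LPS vs NS, 5885 to 6050 and 2873 to 2976 for IL4 vs NS, 3107 to 3262 and 5231 to 5359 for LPS with JQ1, 2748 to 2882 and 4944 to 5167 for LPS with SF2523, 3056 to 3162 and 5523 to 5571 for IL4 with JQ1, and 2772 to 3020 and 3597 to 3977 for IL4 with SF2523. For SF2523 vs JQ1 they were 4680 to 4811 and 4020 to 4128 with LPS and 5419 to 5487 and 3403 to 3543 with IL4, and for the differences between stimuli 3091 to 3364 and 2496 to 2721 (JQ1) and 926 to 1113 and 2393 to 2936 (SF2523).

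The number of the 18 lists called rose with fry from 11 to 18 for LPS vs NS, 11 to 18 for LPS with JQ1, 7 to 18 for LPS with SF2523, 9 to 17 for IL4 with JQ1, 6 to 14 for IL4 with SF2523, 10 to 17 and 8 to 17 for SF2523 vs JQ1 with LPS and IL4, and 9 to 16 for the SF2523 difference. With an estimated correlation it fell from 13 to 6 for IL4 vs NS and from 10 to 5 for SF2523 vs JQ1 with LPS. Fry asks another question, and the cause of the other changes was not tested.

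Overlaps counted only at 2-fold or more were smaller by construction. Genes higher with LPS and lower with JQ1 went from 4638 to 776, lower and higher from 2678 to 202. For SF2523 they went from 2835 to 127 (1804 with median-ratio scaling) and from 1225 to 17 (2077). Shared JQ1 and SF2523 rises under LPS went from 1240 to 23 (2049 with median-ratio scaling) and falls from 2987 to 129 (1956). With IL4, higher and lower with JQ1 went from 5289 to 959, lower and higher from 2586 to 240 (3993 with median-ratio scaling). For SF2523 they went from 2434 to 74 and from 1143 to 19 (1799 with median-ratio scaling). Shared rises went from 1205 to 20 and shared falls from 2312 to 75. The cause of the changes with median-ratio scaling was not tested.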

Other observations

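Nothing in this part was tested for a cause, and the genes outside the marker lists were chosen only after their values were seen. Some markers of granulocyte precursors, osteoclasts and B cells were lower with JQ1, though the neutrophil and precursor list went both ways (3 higher and 6 lower with LPS, 5 and 4 with IL4). S100a8 was at 573 ± 31.7 RPKM with LPS and 725.3 ± 74.1 with JQ1 added. Mpo was lower with JQ1, at 1.83 ± 0.182 RPKM with LPS and 3.11 ± 0.0708 with IL4, than with the stimulus alone (39.9 ± 0.446 and 50.1 ± 1.06), and SF2523 libraries were at 42.7 ± 1.14 and 51.4 ± 1.96 (SD, n = 3). The antimicrobial peptide gene Camp was at 13.4 ± 0.545 RPKM with LPS, 0.366 ± 0.13 with JQ1 added and 15.0 ± 0.325 with SF2523 added. Acp5, the acid phosphatase of osteoclasts, was at 36.1 ± 1.26 RPKM with LPS, 3.55 ± 0.306 with JQ1 added and 39.3 ± 0.755 with SF2523 added. Elane, neutrophil elastase, was at 61.0 ± 0.609 RPKM with LPS, 14.2 ± 0.98 with JQ1 and 72.8 ± 1.82 with SF2523. Cd79b, a B cell receptor component, was at 0.678 ± 0.0725 RPKM in NS, 19.8 ± 0.127 with LPS, 10.4 ± 0.786 with IL4, and 1.63 ± 0.205 and 0.766 ± 0.196 with JQ1 added. Ighm, the other B cell marker that was tested, was at 17.0 ± 0.977 RPKM in NS, 11.4 ± 0.0628 with LPS, 16.2 ± 0.351 with IL4, and 11.9 ± 0.389 and 16.7 ± 0.398 with JQ1 added. The eosinophil markers Prg2 and Ccr3 were at 4.21 ± 0.31 and 1.77 ± 0.0452 RPKM with LPS, against 1.25 ± 0.251 and 0.0329 ± 0.00869 in NS. Of the fibroblast markers, Sparc was at 5.49 ± 8.09 RPKM and Col1a1 at 1.59 ± 1.6 with LPS, where LPS replicate 3 made the spread, and Sparc at 1.57 ± 0.119 in NS.

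Ribosomal protein genes took 4.08% of assigned reads in IL4 with SF2523 and 3.45% in IL4, 3.20% in LPS with SF2523 and 2.14% in LPS, 2.54% and 2.86% in LPS and IL4 with JQ1 and 2.77% in NS. Fold changes with SF2523 followed gene size in both stimuli. Across genes, Spearman's rho with exon length was -0.465 with LPS and -0.395 with IL4, against 0.159 for IL4 with JQ1 vs IL4. With LPS, the rho was -0.246 for exon length given the genomic span and -0.173 for the span given exon length. LPS with JQ1 and IL4 with JQ1 differed from NS by 2452 higher and 3014 lower and by 3064 higher and 1645 lower genes by limma, of which 117 and 75, and 146 and 79, reached 2-fold.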
